A study of Homo sapiens with 15 samples.

How the data were processed

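Gene expression was measured by RNA-seq in 15 libraries of 3 human luminal breast cancer cell lines, CAMA1, MCF7 and T47D, which are oestrogen receptor positive and HER2 negative. Each line gave 1 library of untreated cells in log-phase growth and 1 library after each of 2, 7, 10 and 14 days in 500 nM palbociclib, an inhibitor of the cyclin-dependent kinases CDK4 and CDK6. Per the labels' protocols, treated cells pooled from 3 wells were collected at each time, RNA was purified on silica columns, and libraries were made with a stranded mRNA kit. For the untreated libraries no number of wells was recorded here. The control cells were collected alongside the day 2 cells. They are called untreated in the sample labels and vehicle treated in the protocol and design text, so whether they received vehicle is not settled here. No untreated library of days 7, 10 or 14 was analysed here, so days in the drug and days in culture go together in those comparisons.

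The deposited table holds TPM, an abundance scaled for transcript length and library total, per gene symbol, the authors' own values. Per the submitters' processing notes, Bowtie2 2.2.5, RSEM 1.2.20 and the genome build hg19 were used. The gene annotation, the strand setting and other options are not given in the sources used here. TPM sums to the same total in each library and keeps no read depth, so the depth behind each value is unknown and no counting interval is given. A rise of a few abundant transcripts lowers all others on this scale. RSEM is built to divide reads that match several genes between them. Values of near-identical genes (HLA class I genes, replication-dependent histones, tubulins, MTRNR2L genes) are therefore less certain than others. How well the mRNA kit captured histone transcripts was not measured. Coordinates are not given, because the reference annotation used for gene names (GRCh38.p14) is of another build than the table.

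The table has 23686 rows. Of these, 28 bore dates in place of gene symbols and were left out, since they name no gene; they held between 0.0872% and 0.142% of the TPM of a library. Of the 23658 genes left, 3501 were at 0 in every library. Genes with at least 1 TPM in at least 3 libraries were tested, 14195 in all. Every column of the table was mapped to a sample by its label, and 0 columns were left unused.

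Values were analysed as log2(TPM + 1), so each log2 difference is on that scale and understates the change of genes with low values. The main test was limma 3.58.1 with an intensity trend in R 4.3.3 (matrixStats 1.5.0, jsonlite 2.0.0), with the 5 conditions and the cell line as terms over all 15 libraries (8 residual degrees of freedom and 3.18 prior degrees of freedom). The comparisons were the mean of the 4 treated conditions against untreated, each day against untreated, days 7 to 14 against day 2, and day 14 against day 7. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. The cell lines are the replicates (n = 3 lines), so the test asks for a response shared by the lines. The error includes differences between their responses. Each SE comes from this error, pooled over all 15 libraries, and is not the standard error of 3 line values. Contrasts that average days take the days of a line as independent. These days share the line's response and, against untreated, its 1 untreated library, so such SEs and p-values may be too small. A separate limma model with a line by treatment term (9 residual degrees of freedom) tested whether the response differed between lines, with the 4 days of each line as repeats, which are different times and not independent cultures. In every comparison with limma, p-values measure the spread between these libraries.

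Cell line was in the model as a block because the libraries of a line come from the same cells. The pairing was checked: the correlation of deviations from the condition means was at least 0.462 in all 30 pairs of libraries of the same line (median 0.793). Gene lists were fixed before the data were examined, 32 in all, and their entries were all found in the table, 899 as written and 6 by an older symbol. The 30 lists with at least 5 tested members were tested with camera at a preset correlation of 0.01 between genes, with camera at an estimated correlation and with fry. Lists of fibroblast and blood cell markers had 4 tested members each and were described by their values. A limma test on the mean log2 value of each list's members, adjusted over the 30 lists, was added after the data were seen. A list's median log2 ratio in 1 library was placed among 10000 random lists matched on expression, as a description of that library.

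The rule for the named genes was also fixed beforehand. It takes called genes with a mean of at least 5 TPM that moved in the same direction in all treated libraries (the averaged comparison, the 12 largest changes each way) or in all 3 lines (the 4 largest each way for a single day, and the 8 largest for days 7 to 14 against day 2), up to 4 members of each list by p, and a set of cell cycle, senescence, oestrogen receptor, antigen presentation and growth factor genes reported whatever their result. For the difference between lines it takes the 12 called genes of lowest adjusted p whose mean log2 ratio differs by at least 1 between lines.

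Scripts were tested on simulated data made from the real genes' means and spread. For the averaged comparison, 52% of genes changed 2-fold and 92% of genes changed 4-fold were recovered, and 7.10% of calls were false. For day 7 against untreated these values were 24%, 81% and 4.55%, and for days 7 to 14 against day 2 they were 46%, 87% and 7.64%. For the difference between lines, 1% and 23% were recovered, with 4.00% of calls false. That simulation used the spread left by the main fit and no change with day, which counts as error in the line test. Its values are therefore not the recovery of that test on the data. With no list changed, camera called 0 of 30 simulated lists. Simulated noise was drawn independently for each gene and library. In the data the estimated correlation within a list reached 0.879, so this does not test camera's false calls where members vary together.

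The alternatives tried were no cell line term, quantile normalization, centring each library on its median, no filter, a filter of 5 TPM, pseudocounts of 0.1 and 5, limma without trend and with robust empirical Bayes, leaving out each line in turn, and, for the difference between lines, leaving out day 2. Leaving out the CAMA1 day 14 library, the T47D day 7 library and both was added after the data were seen, because these libraries stood apart from the others of their line. A fit with array weights, also added then, did not converge and is not reported.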

Results

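RNA-seq profiles of 3 oestrogen receptor positive luminal breast cancer cell lines (CAMA1, MCF7 and T47D) were compared before and after 2, 7, 10 and 14 days in 500 nM palbociclib, which blocks the kinases that pair with D-type cyclins to drive cells from G1 into S phase. Each line had 1 untreated library and 1 library per day, 15 in all, so each condition had n = 3 lines and no condition was repeated within a line. Values are TPM, whose sum is fixed, and the read depth is unknown. Between 12102 and 13223 genes reached 1 TPM in a library. Libraries separated mainly by line, and the first 3 principal components held 37.8%, 31.4% and 11.9% of the variance. The CAMA1 day 14 and T47D day 7 libraries stood apart from the rest of their lines. The lowest Spearman correlation within a line was 0.848 in CAMA1 and 0.881 in T47D, and both pairs included that library. In CAMA1 day 14 the 20 most abundant genes held 25.2% of the TPM, against 9.67% to 15.9% in the other libraries, and the median log2 ratio of all tested genes to untreated was -0.35.

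The design asked first how the lines respond to palbociclib whatever the day. Averaged over the 4 days, genes of cell division fell in all 3 lines. The mitotic kinase gene AURKB fell by 3.45 ± 0.58 (log2 ± SE of the limma fit, n = 3 lines, adjusted p = 0.0103). The ribonucleotide reductase subunit gene RRM2 fell by 3.37 ± 0.85 (adjusted p = 0.0425). The cyclin gene CCNA2 fell by 3.20 ± 0.65 (adjusted p = 0.0206) and the proliferation marker MKI67 by 3.12 ± 0.72 (adjusted p = 0.0317). The chromatin protein gene HMGB2 fell by 2.99 ± 0.25 (adjusted p = 0.000497). Also among the 12 largest decreases named by the rule were TYMS (-3.18), TROAP (-3.04), NUSAP1 (-3.02), KIAA0101 (-2.99), PTTG1 (-2.99), TOP2A (-2.97) and PBK (-2.88). Each was lower in 12 of 12 treated libraries, as the rule requires. CDK1 (-2.65) and LMNB1 (-2.47), the lamin B1 gene, fell too, while E2F1 (-1.87, adjusted p = 0.0803) and MCM2 (-1.46, adjusted p = 0.0810) did not pass the limma test.

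Of 42 tested genes of mitosis and G2/M, 21 fell and 0 rose, among them CDC25C (-1.97), FOXM1 (-2.80) and SPC25 (-1.70). Adjusted over the list alone, all 42 fell. Of 47 genes of DNA replication and S phase, 20 fell and 0 rose, including PRIM1 (-2.57), CDT1 (-2.43), DUT (-1.62) and CCNE2 (-2.0), and 40 fell when adjusted over the list alone. CCNE2 was at adjusted p = 0.0506 without T47D day 7. Of 26 genes of homologous recombination and fork repair, 10 fell and 0 rose, including RAD51AP1 (-1.91), CHEK1 (-1.58), FANCA (-1.67) and BRIP1 (-0.92), and 24 fell when adjusted over the list alone. As sets, these 3 lists were lower than other genes by camera (adjusted p = 3.90e-21, 2.95e-20 and 4.66e-13), a call lost for each (adjusted p = 0.325 with an estimated correlation). Fry called all 3 (adjusted p = 0.0380, 0.0381 and 0.0381). Their mean scores fell by 2.17 ± 0.55, 1.58 ± 0.44 and 1.31 ± 0.35 in the limma test of list means (adjusted p = 0.0262 for each). The mitotic decrease was deepest in the 2 libraries that stood apart: the median log2 ratio of mitotic genes was -3.84 in CAMA1 day 14 and -4.14 in T47D day 7, against -2.76 to -0.90 in the other 10 treated libraries. In these 2 libraries DNA replication genes had medians of -3.10 and -2.73 and homologous recombination genes -2.65 and -2.38.

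**Figure D1:**
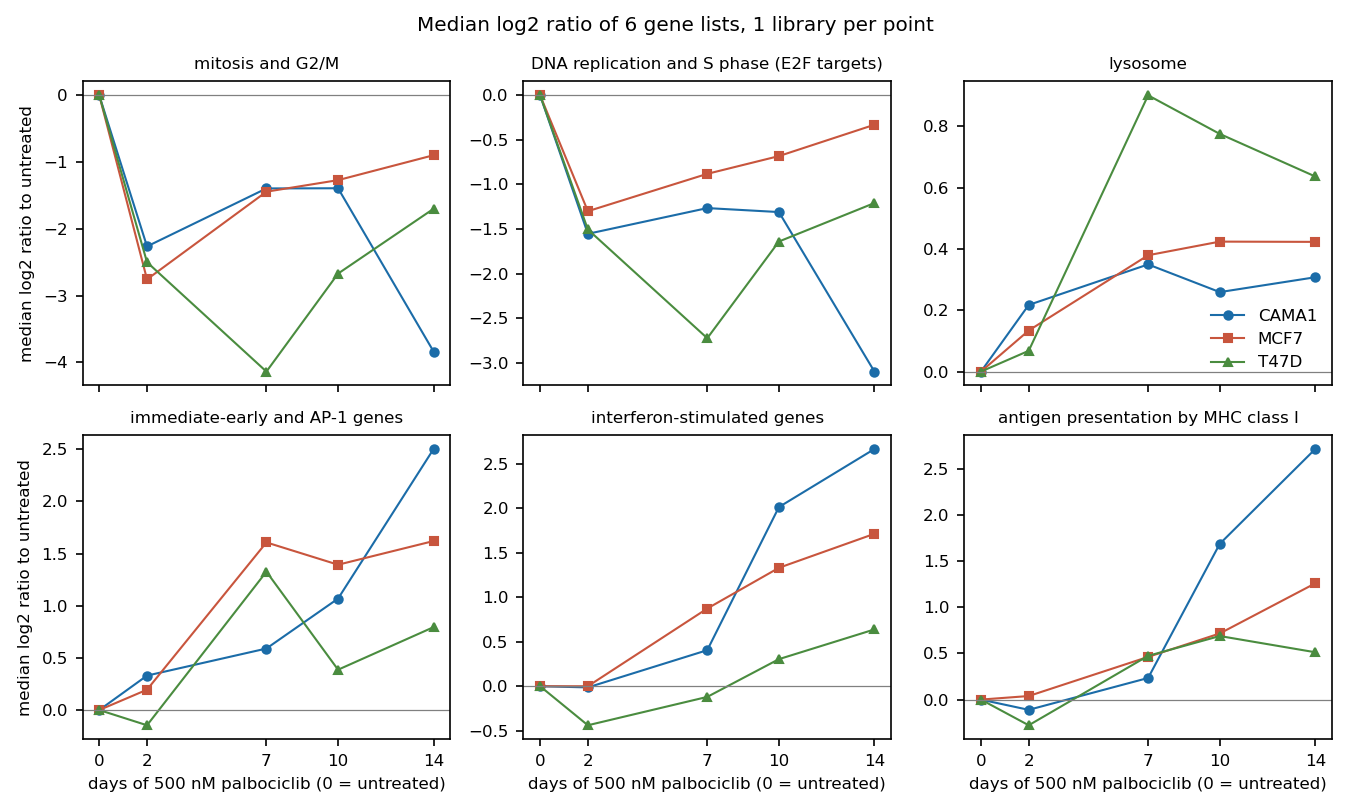
Median log2 ratio to the untreated library of the same line (vertical axis) for the tested members of 6 gene lists, by days in 500 nM palbociclib (horizontal axis, 0 is untreated); each point is 1 library and each line joins the libraries of 1 cell line. Mitotic genes lay between -4.14 and -0.90 in all 12 treated libraries, and interferon-stimulated genes lay highest in CAMA1 day 14, at 2.66.

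Increases were led by immediate-early genes. The AP-1 subunit genes FOSB and FOS rose by 3.87 ± 0.41 (adjusted p = 0.00234) and 3.07 ± 0.44 (adjusted p = 0.00579), and the MAP kinase phosphatase gene DUSP1 by 2.07 ± 0.17 (adjusted p = 0.000497). FOSB went from 0.57, 0.76 and 0.64 TPM in untreated CAMA1, MCF7 and T47D cells to 24.7, 85.7 and 77.1 TPM at day 14. Of 21 immediate-early and AP-1 genes, 7 rose and 0 fell, with JUN (1.74) and JUNB (1.58) among them, and 10 rose when adjusted over the list alone. The list was higher by camera (adjusted p = 1.52e-08; adjusted p = 0.233 with an estimated correlation), and its mean score rose by 1.11 ± 0.24 (adjusted p = 0.0262). Its median was 2.50 in CAMA1 day 14 and 1.33 in T47D day 7. The other large increases named by the rule were in genes higher in 12 of 12 treated libraries, as the rule requires. They were RND3 (2.71) and RND1 (2.12), which encode Rho family GTPases, the netrin gene NTN4 (2.64) and EPAS1 (2.32), which encodes a hypoxia-inducible factor subunit. ANXA3 (2.29), the NADPH oxidase subunit gene NCF2 (2.28), the tubulin gene TUBA1A (2.18, with near-identical paralogs), FAM189A2 (2.07) and the cathepsin gene CTSO (2.02) made up the rest.

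Of 50 lysosomal genes, 6 rose and 0 fell, including the protease cathepsin D gene CTSD (1.52 ± 0.30, adjusted p = 0.0184), PSAP (1.34), GAA (0.80) and NPC2 (0.54), and 9 rose when adjusted over the list alone. Of 29 autophagy genes, 3 rose and 0 fell, OPTN (1.35), TP53INP2 (1.45) and WIPI1 (1.04), the same number as when adjusted over the list alone. Both lists were higher by camera (adjusted p = 6.19e-09 and 1.01e-05), calls lost at adjusted p = 0.269 and adjusted p = 0.307 with an estimated correlation, while the limma test of list means gave rises of 0.41 ± 0.12 and 0.44 ± 0.14 (adjusted p = 0.0262 and 0.0371). Their medians were 0.31 and 0.46 in CAMA1 day 14 and, highest of all libraries, 0.90 and 0.76 in T47D day 7. Of 26 genes of the extracellular matrix and TGF-beta response, 4 rose and 0 fell, namely TGFB2 (2.96), CYR61 (1.75), ID3 (1.46) and LAMB1 (1.16), with 6 adjusted over the list alone. That list was higher by camera (adjusted p = 7.16e-06; adjusted p = 0.307 with an estimated correlation) and by its mean (0.80 ± 0.22, adjusted p = 0.0262).

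Within the CDK4/6 and RB axis, members moved both ways. CDK6, the gene of a kinase that palbociclib inhibits, rose by 1.78 ± 0.37 (adjusted p = 0.0227), and the kinase inhibitor gene CDKN2B rose by 1.77 ± 0.34 (adjusted p = 0.0162). The related inhibitor genes CDKN2C and CDKN2D fell by 2.13 ± 0.33 and 1.66 ± 0.31 (adjusted p = 0.00832 and 0.0149), and the RB family gene RBL1 fell by 1.40 ± 0.27 (adjusted p = 0.0184). Thus 2 of 19 members rose and 3 fell, with 2 and 4 adjusted over the list alone. CCND1 (0.46), CCNE1 (0.52), CDK2 (-1.29), CDK4 (-0.17), RB1 (-0.32), RBL2 (0.14), CDKN1A (0.45), CDKN1B (-0.35) and CDKN2A (-0.43) did not pass. CDKN2A was at 0.32 TPM or less in all 5 MCF7 libraries and between 9.18 and 40.0 TPM in the others.

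**Figure D2:**
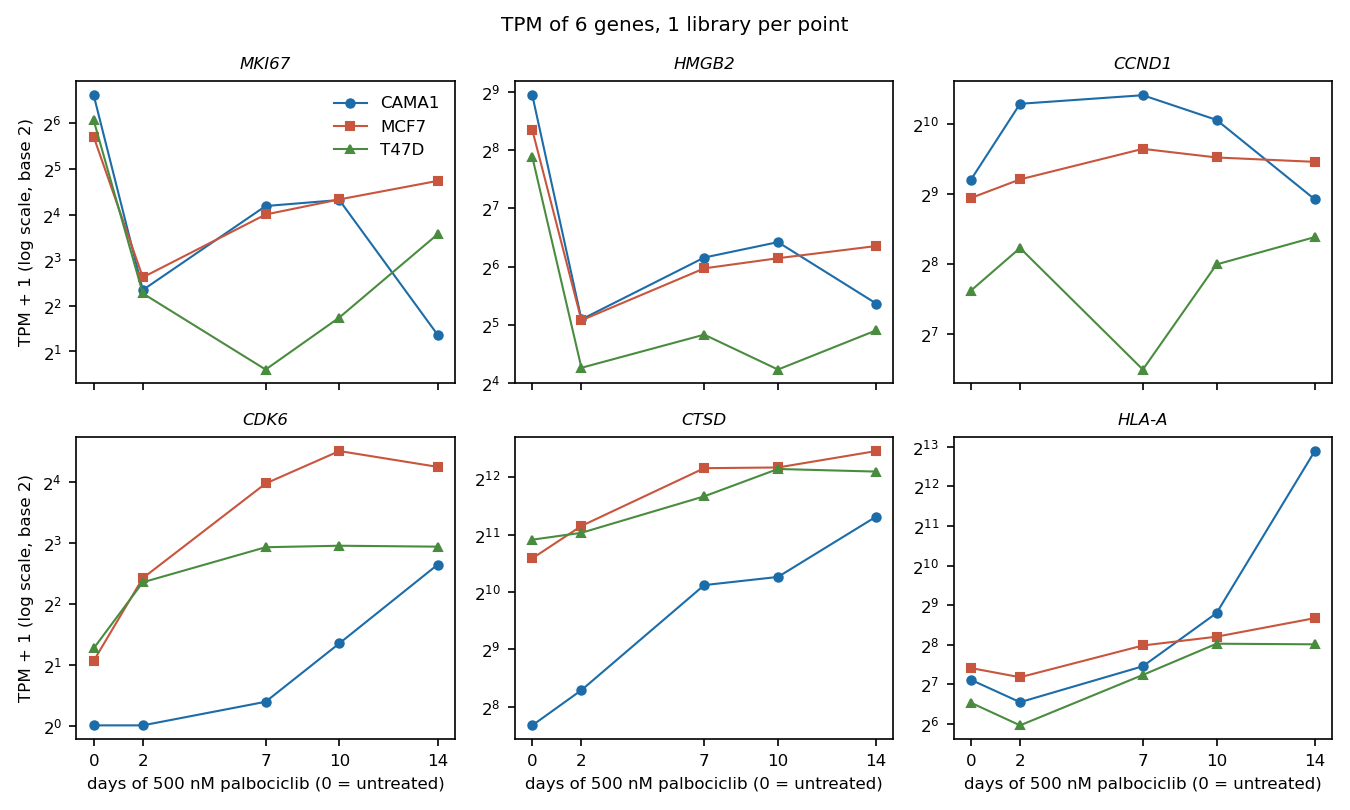
TPM plus 1 on a log axis of base 2 (vertical) for 6 genes, by days in 500 nM palbociclib (horizontal, 0 is untreated); each point is 1 library and each line joins the libraries of 1 cell line. MKI67 went from 97.1, 51.1 and 66.0 TPM in untreated CAMA1, MCF7 and T47D cells to 4.09, 5.17 and 3.83 TPM at day 2, and CDK6 was higher at day 14 than in untreated cells in each line.

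Several other lists were called by camera with few members passing the gene test. Of 41 interferon-stimulated genes, 3 rose (OAS2 1.54, PARP9 1.29, DDX58 1.04), with 4 adjusted over the list alone. Of 19 genes of antigen presentation by MHC class I, 1 rose (ERAP1 1.19), with 1 adjusted over the list alone. NF-kappaB targets had 1 of 20 (RELB 1.48; 4 adjusted over the list alone), senescence-associated secretory factors 0 of 20 (0 adjusted over the list alone) and basal and mesenchymal genes 1 of 20 (LAMC2 2.08; 1 adjusted over the list alone). Camera's adjusted p values for these 5 lists were 5.37e-08, 0.000169, 3.12e-05, 0.00630 and 0.0126, and all were lost, at adjusted p = 0.325, 0.505, 0.325, 0.505 and 0.505 with an estimated correlation. In CAMA1 day 14 their medians were 2.66, 2.72, 4.06, 3.35 and 2.13, and in T47D day 7 they were -0.12, 0.47, -0.24, 0.01 and -0.02. In this averaged comparison, none of the 5 passed the limma test of list means (adjusted p = 0.0849, 0.182, 0.112, 0.168 and 0.191). At day 14 alone against untreated, all 5 were higher by that test (adjusted p = 0.0106, 0.0248, 0.0106, 0.0183 and 0.0289). Without CAMA1 day 14 and T47D day 7, basal and mesenchymal genes no longer passed at day 14 (adjusted p = 0.121). The other 4 lists did (adjusted p = 0.0164 for each).

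Camera also placed 4 further lists higher: receptor tyrosine kinase and growth factor signalling (PIK3IP1 1.25 and FGFR2 0.98 rose; 2 adjusted over the list alone), hypoxia (EGLN3 1.36 and P4HA2 0.88 rose; 3 adjusted over the list alone), regulators of apoptosis (MCL1 0.92 rose; 1 adjusted over the list alone) and the unfolded protein response (0 of 19; 0 adjusted over the list alone). Their adjusted p values were 0.00630, 0.0124, 0.0277 and 0.0277, lost at adjusted p = 0.233, 0.307, 0.307 and 0.681 with an estimated correlation, and by list means only the first rose (0.30 ± 0.09, adjusted p = 0.0262). Their medians were 0.44, 0.55, -0.04 and 0.53 in CAMA1 day 14 and 0.36, 1.36, 0.58 and 1.55 in T47D day 7. Camera placed 5 lists lower. Ribosomal proteins had RPL18 (-0.53) lower, with 3 adjusted over the list alone. Oxidative phosphorylation had 0 of 39, with 0 adjusted over the list alone. Ribosome biogenesis and MYC targets had EIF4EBP1 (-1.14) and FBL (-0.94) lower, with 2 adjusted over the list alone. In the ATF4 and amino acid response, the serine metabolism genes PHGDH (-2.31) and SHMT2 (-1.04) fell. Adjusted over the list alone, 1 of its members rose and 5 fell. Replication-dependent histones had HIST1H2BO (-1.80) lower, with 4 adjusted over the list alone. Adjusted p values were 1.47e-06, 0.000284, 0.00232, 0.0115 and 0.0151, and these too were lost, at adjusted p = 0.530 for ribosomal proteins and adjusted p = 0.631 for the other 4 with an estimated correlation. None of the 5 passed the limma test of list means (adjusted p = 0.129, 0.222, 0.222, 0.362 and 0.209). In CAMA1 day 14 their medians were -0.85, -1.06, -0.99, -0.49 and 0.00, and in T47D day 7 they were -0.50, -0.63, -0.51, 1.07 and 0.05. Oxidative phosphorylation genes had medians between -0.34 and 0.05 in the other 10 treated libraries, and ribosomal protein genes between -0.46 and 0.17. PHGDH fell most in MCF7 (-4.04, against -1.19 in CAMA1 and -1.69 in T47D).

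The remaining 9 lists were not called by camera. Among oestrogen receptor targets, FOS and CTSD rose and IL17RB (-1.80) fell, 3 of 35 members (3 adjusted over the list alone), and ESR1 (-0.69), PGR (-0.37), TFF1 (0.89) and GREB1 (-0.34) did not pass. Among p53 targets, BTG2 (2.04) and TP53INP1 (1.36) rose and DDB2 (-1.36) and FDXR (-0.93) fell, 4 of 22 members (6 adjusted over the list alone). Luminal genes included ELF3 (1.17), CLDN4 (0.80) and CD24 (1.0) that rose (3 adjusted over the list alone). The CDK4/6 and RB axis, cholesterol biosynthesis (EBP -0.85 fell), fatty acid synthesis (0 of 22), fatty acid oxidation (ACOX1 0.71 rose and ECI1 -0.73 fell), glycolysis (SLC2A1 0.89 rose, with adjusted p = 0.0562 without T47D day 7) and cilium (TCTN1 0.71 rose) made up the rest; adjusted over the list alone, 3, 0, 2, 0 and 1 members of the last 5 were called. Directions of camera, median and mean differed for p53 targets, oestrogen receptor targets and cilium, whose means lay between -0.01 and 0.12. MYC (-0.45), GLB1 (0.59), SERPINE1 (1.07), IL8 (1.02), B2M (0.82), HLA-A (1.06), STAT1 (0.65), IFIT1 (1.11), SQSTM1 (1.05), LAMP1 (0.33), BCL2 (-0.60), BCL2L1 (0.79), EGFR (0.82), ERBB2 (0.61), ERBB3 (-0.06), FGFR1 (0.03) and IGF1R (0.41) did not pass either.

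In total limma called 872 genes in the averaged comparison, 350 higher and 522 lower, of which 162 and 269 changed at least 2-fold. Of the 872, 871 moved in the same direction in all 3 lines. The test favours this, since differences between lines count as error, so it is no separate evidence that the lines agree. The count was 0 without MCF7, 35 without T47D and 616 without CAMA1. It was 1994 without the CAMA1 day 14 library and 2934 without that and T47D day 7. The fit without MCF7 kept both of these libraries among fewer libraries, while the fit without CAMA1 dropped CAMA1 day 14. The counts without a line therefore cannot tell which lines the calls rest on. With no cell line block the count was 5.

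At day 2, the earliest time and the only one with control cells collected alongside, HMGB2 fell by 3.58 ± 0.32 (adjusted p = 0.00264), from 492, 325 and 235 TPM to 33.1, 32.8 and 18.2 TPM in CAMA1, MCF7 and T47D. The primase gene PRIM1 fell by 2.66 ± 0.34, the MAX partner gene MXD3 by 2.46 ± 0.34 and the kinetochore gene KNTC1 by 1.72 ± 0.27 (adjusted p = 0.0330, 0.0330 and 0.0444). FOSB rose by 3.21 ± 0.52 (adjusted p = 0.0469). Limma called 1 gene higher and 18 lower. Without the CAMA1 day 14 library, which bears here only on the shared error, it called 417, without T47D day 7 139, without both 812, and between 0 and 1 without any 1 line. It called 0 with no cell line block.

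After 7 days, FOSB (3.40 ± 0.52, adjusted p = 0.0168), the lipocalin apolipoprotein D gene APOD (3.29 ± 0.60, adjusted p = 0.0275), the growth factor gene TGFB2 (3.18 ± 0.64, adjusted p = 0.0368) and RND3 (2.90 ± 0.64, adjusted p = 0.0497) rose most. AURKB (-3.61 ± 0.74, adjusted p = 0.0388), KIAA0101 (-3.17 ± 0.68, adjusted p = 0.0452), PTTG1 (-3.01 ± 0.67, adjusted p = 0.0499) and FOXM1 (-2.87 ± 0.62, adjusted p = 0.0459) fell most, with AURKB at -5.89 in T47D against -2.69 in CAMA1 and -2.25 in MCF7. CDKN2C (-2.18) and HMGB2 (-2.74) fell too. Without the T47D day 7 library FOSB and HMGB2 passed, but APOD (3.54), TGFB2 (3.65), RND3 (2.29), AURKB (-2.77), KIAA0101 (-2.36), PTTG1 (-2.42), FOXM1 (-2.24) and CDKN2C (-1.83) did not (adjusted p = 0.0664, 0.0636, 0.174, 0.131, 0.143, 0.179, 0.155 and 0.127). Of 263 called genes, 119 were higher and 144 lower. The split was 236 higher and 375 lower with quantile normalization, 248 higher and 425 lower with libraries centred on their medians, 85 higher and 157 lower with a pseudocount of 5, and 142 higher and 128 lower with a pseudocount of 0.1. The count was 45 (24 higher and 21 lower) without the T47D day 7 library, 1614 without CAMA1 day 14 and 1033 without both, and it was 0 without MCF7, 1 without T47D, 522 without CAMA1 and 0 with no cell line block.

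After 10 days, SERPINA3, an acute-phase protease inhibitor gene, rose by 4.77 ± 1.04 (adjusted p = 0.0391), from 4.40, 36.6 and 16.6 TPM to 568, 371 and 339 TPM in CAMA1, MCF7 and T47D. TGFB2 (4.08 ± 0.64), FOSB (3.79 ± 0.52) and APOD (3.68 ± 0.60) rose as well (adjusted p = 0.0134, 0.0112 and 0.0152), and so did CDK6 (2.15) and CTSD (1.80). PTTG1 (-3.03 ± 0.67), HMGB2 (-2.79 ± 0.32), PRIM1 (-2.53 ± 0.34) and SNORD22 (-5.40 ± 1.16) fell (adjusted p = 0.0424, 0.00737, 0.0105 and 0.0380). SNORD22 is a small nucleolar RNA, a class that mRNA libraries capture poorly, so its TPM is uncertain. Of 387 called genes, 238 were higher and 149 lower, a split that became 292 higher and 322 lower with quantile normalization and 311 higher and 352 lower with libraries centred on their medians. The count was 1583 without CAMA1 day 14, 648 without T47D day 7 and 2758 without both, and it was 0 without MCF7, 0 without T47D, 80 without CAMA1 and 0 with no cell line block.

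At 14 days, the 4 largest increases named by the rule were in genes that also belong to the set chosen as high in CAMA1 day 14. S100A9, a calcium-binding protein gene of inflammation, rose by 8.25 ± 1.51 (adjusted p = 0.0208), the complement gene CFB by 7.33 ± 1.53 (adjusted p = 0.0323), the lipocalin gene LCN2 by 7.25 ± 1.69 (adjusted p = 0.0435) and SAA1, of serum amyloid A, by 6.97 ± 1.58 (adjusted p = 0.0410). The size differed by line: S100A9 went from 3.23 to 26842 TPM in CAMA1, from 1.15 to 1404 TPM in MCF7 and from 15.2 to 110 TPM in T47D. AURKB (-2.97 ± 0.74), HMGB2 (-2.85 ± 0.32), the meiotic recombination gene MND1 (-2.65 ± 0.57) and WDR76 (-2.63 ± 0.58) fell (adjusted p = 0.0498, 0.00382, 0.0352 and 0.0369). CDK6 (2.49), CTSD (2.23) and the interferon signalling gene STAT1 (1.23, adjusted p = 0.0407) rose, and CDKN2C (-2.23) and RBL1 (-1.40) fell. Without CAMA1 day 14, S100A9, HMGB2, CTSD and CDKN2C passed, but CFB (5.35), LCN2 (5.68), SAA1 (4.44), AURKB (-2.0), MND1 (-1.87), WDR76 (-1.77), CDK6 (2.06), RBL1 (-0.88) and STAT1 (1.19) did not (adjusted p = 0.0700, 0.121, 0.0513, 0.122, 0.0709, 0.0570, 0.0597, 0.0781 and 0.0843).

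IL6, too low to be tested, was at 6.49 TPM in CAMA1, 5.52 in MCF7 and 0 in T47D at day 14, and listed at 0 in all 3 untreated libraries. Of 568 genes called at day 14, 298 were higher and 270 lower, a split that became 402 higher and 431 lower with quantile normalization, 421 higher and 472 lower with libraries centred on their medians, and 229 higher and 293 lower with a pseudocount of 5. The median log2 difference of all tested genes was -0.10. The count was 308 (193 higher and 115 lower) without CAMA1 day 14, 880 without T47D day 7 and 950 without both, and it was 0 without MCF7, 61 without T47D, 13 without CAMA1 and 2 with no cell line block.

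Longer exposure (days 7 to 14) was then set against day 2. APOD rose by 3.58 ± 0.49 (adjusted p = 0.0496), the death receptor gene TNFRSF21 by 1.79 ± 0.19 (adjusted p = 0.0132), OLFM2 by 1.55 ± 0.19 (adjusted p = 0.0257) and the peptidase gene CPQ by 1.5 ± 0.19 (adjusted p = 0.0257), each in 3 of 3 lines, as the rule requires. Without T47D day 7, TNFRSF21 alone passed (adjusted p = 0.0785 for APOD, 0.0709 for OLFM2 and 0.0747 for CPQ). No other gene passed in limma, and 1962 had an unadjusted p under 0.05. Adjusted over the list alone, 31 of 41 interferon-stimulated genes were higher, among them OAS2 (2.12), DTX3L (1.55), DDX58 (1.43) and IFITM3 (1.41), as were 14 of 19 MHC class I genes, 10 of 20 NF-kappaB targets and 8 of 21 immediate-early genes, while 36 of 40 ribosomal protein genes were lower; 0 of these passed over all genes.

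Camera called 20 of 30 lists in this comparison, 14 higher and 6 lower. Interferon-stimulated genes (adjusted p = 1.02e-20), MHC class I (2.10e-09), NF-kappaB targets (2.42e-09) and extracellular matrix genes (6.73e-08) were the 4 most clearly higher, and ribosomal proteins (1.43e-30) and oxidative phosphorylation (3.54e-15) the most clearly lower. These calls were lost, at adjusted p = 0.145, 0.212, 0.158, 0.145, 0.145 and 0.261 with an estimated correlation. Fry called all of these but oxidative phosphorylation (adjusted p = 0.0137, 0.0407, 0.0160, 0.0155, 0.0137 and 0.151). By list means, limma gave rises of 1.39 ± 0.31, 1.18 ± 0.37, 1.57 ± 0.45 and 0.91 ± 0.23 for the former 4 and a fall of 0.45 ± 0.12 for ribosomal proteins (adjusted p = 0.0243 for each); oxidative phosphorylation (-0.40) did not pass. Library medians for interferon-stimulated genes at day 14 were 2.66 in CAMA1, 1.71 in MCF7 and 0.64 in T47D, against -0.01, 0.00 and -0.44 at day 2. Day 14 was the highest of the later days: relative to untreated, the list's mean was -0.26, 0.43, 1.21 and 1.75 at days 2, 7, 10 and 14.

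Secretory factors of senescence (mean 1.18), basal and mesenchymal genes (0.94), immediate-early genes (0.90), hypoxia (0.63), autophagy (0.48), lysosome (0.39), regulators of apoptosis (0.39) and receptor tyrosine kinase signalling (0.32) were higher by camera and by list means. Their camera calls were lost, at adjusted p = 0.212, 0.212, 0.145, 0.145, 0.203, 0.183, 0.145 and 0.145 with an estimated correlation. Fry called each of these lists (adjusted p between 0.0137 and 0.0407). Camera alone called the unfolded protein response (mean 0.50) and histones (0.48) higher and cholesterol biosynthesis (-0.28), fatty acid synthesis (-0.14), fatty acid oxidation (-0.14) and ribosome biogenesis (-0.21) lower, calls lost at adjusted p = 0.524, 0.522, 0.278, 0.361, 0.297 and 0.480 with an estimated correlation. Of fatty acid synthesis genes, 2 were higher and 0 lower when adjusted over the list alone, although the list was placed lower. The mean of p53 targets rose by 0.45 ± 0.16 by list means (adjusted p = 0.0389) without a camera call. The other 9 lists passed neither test, and camera, median and mean differed in direction for DNA replication and cilium.

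Mitosis, DNA replication and homologous recombination genes did not differ between the later days and day 2 over all libraries, with mean scores of 0.42 ± 0.57, 0.12 ± 0.45 and 0.18 ± 0.37. Without CAMA1 day 14 and T47D day 7 they were higher at the later days by 0.93 ± 0.23, 0.52 ± 0.18 and 0.50 ± 0.14 (adjusted p = 0.0110, 0.0327 and 0.0136), a check added after the data were seen. The gene count was 95 without CAMA1 day 14, 1 without T47D day 7, 290 without both, and 0 without any 1 line, with no cell line block or with libraries centred on their medians. The limma test of list means called 14 lists, but 0 with quantile normalization (lowest adjusted p = 0.0797) and 1 with libraries centred on their medians (ribosomal proteins, -0.54). In each of these 3 settings 14 lists had an unadjusted p under 0.05. The mean of interferon-stimulated genes was 1.24 ± 0.33 with quantile normalization and 1.30 ± 0.37 with centred libraries, that of MHC class I genes 1.10 ± 0.39 and 1.09 ± 0.45, and that of ribosomal proteins -0.33 ± 0.12 and -0.54 ± 0.10.

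Between day 14 and day 7, limma called 0 genes (lowest adjusted p = 0.677), with 946 at an unadjusted p under 0.05. Expression of these genes was therefore not shown to differ between the times; MKI67 was at 15 and 25.7 TPM at days 7 and 14 in MCF7, at 0.52 and 10.9 TPM in T47D, and at 17.2 and 1.58 TPM in CAMA1. The median log2 difference of all tested genes was -0.11, and -0.00 with libraries centred on their medians.

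The last question was whether the response differed between the lines. Limma called 0 of 14195 genes for a line difference (lowest adjusted p = 0.267), with 661 at an unadjusted p under 0.05, and 0 genes in each pair of lines (lowest adjusted p = 0.831 for CAMA1 and MCF7, 0.202 for CAMA1 and T47D, 0.162 for MCF7 and T47D). On simulated data this test recovered 23% of 4-fold differences. The simulated noise had the spread of the main fit and no change with day, so 23% is not the recovery on these data. The lack of calls does not show that the lines responded alike. Without both libraries that stood apart, 3 genes passed (adjusted p = 0.0449 each), chosen here because the count is small: SOD3 (2.37) and ZBTB16 (3.20) were higher and SLFN11 (-2.32) lower with palbociclib in T47D, with values between -0.03 and 0.16 in the other lines. The count was 78 with day 2 left out, 177 with no filter on low values, and between 2 and 3 without any 1 line.

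Across the tested genes, which are not independent replicates, the mean response of each line correlated with that of the others at Pearson's r = 0.463 for CAMA1 and MCF7 (Spearman's rho = 0.449), 0.510 for CAMA1 and T47D (0.487) and 0.411 for MCF7 and T47D (0.386). These lines share no libraries. In all 3 lines, 93 genes were at least 2-fold higher and 190 at least 2-fold lower, against 2.10 and 1.83 for independent lists, while 1274 and 895 passed 2-fold in 1 line only. These are counts by size, not by a test.

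**Figure D3:**
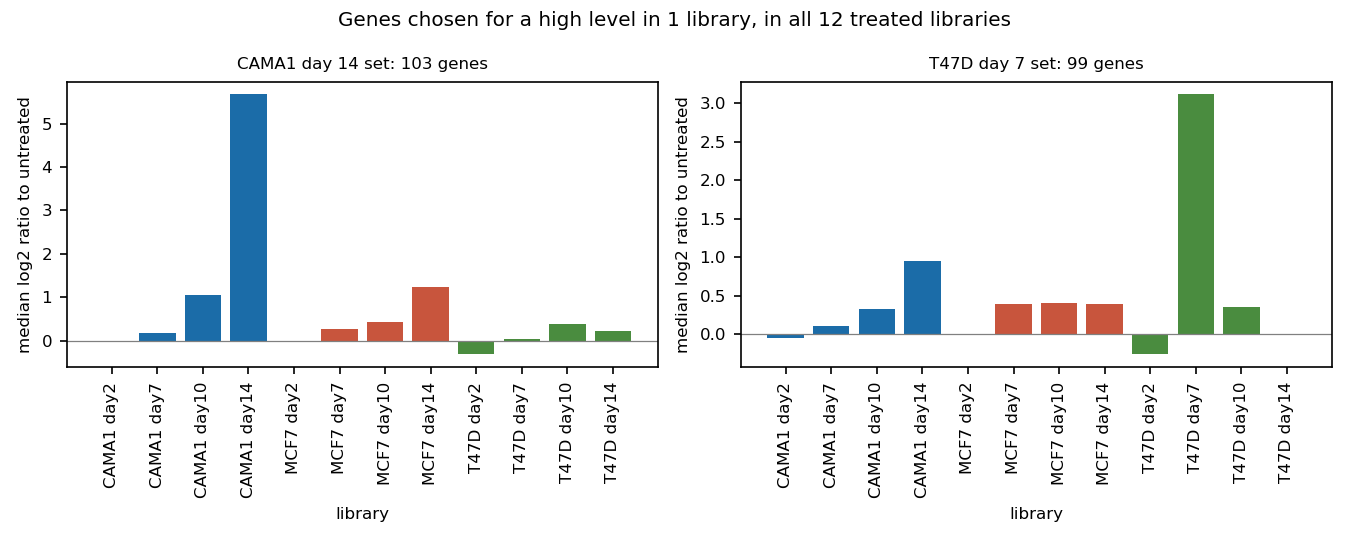
Median log2 ratio to the untreated library of the same line (vertical axis) of 103 genes chosen as high in the CAMA1 day 14 library (left) and 99 chosen as high in the T47D day 7 library (right), in each of the 12 treated libraries (horizontal axis); each bar is 1 library, coloured by cell line. The bars of the libraries used for the choice stand at 5.67 and 3.11 by construction, and the left set reached 1.24 in MCF7 day 14.

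The libraries that stood apart held genes at levels not seen in the others. In CAMA1 day 14, the MHC class II genes CD74 and HLA-DRA were at 3135 and 1151 TPM, against 35.6 and 14.2 TPM at day 10, and HLA-A was at 7608 TPM against 445 TPM. In T47D day 7, the heat-shock gene HSPA6 was at 747 TPM, against 3.08 TPM or less in the other T47D libraries, and the haem oxygenase gene HMOX1 at 2449 TPM, against 32.1 TPM or less; HMOX1 was at 1894 TPM in CAMA1 day 14. Of the values of 13 fibroblast markers 22.6% reached 1 TPM, and of those of 15 blood cell markers 20.9%, with medians of 0.06 and 0.04 TPM. The highest values were 105 TPM (FBLN1, untreated CAMA1) and 65.9 TPM (CD14, CAMA1 day 14). CD14, one of the genes chosen as high in CAMA1 day 14, was at 1.71 TPM or less in the other 14 libraries.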

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

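The tests of mixed cells, shared responses, handling, a single library, time in culture and the size left by other scalings were chosen after the results were seen. The criterion on the adjusted p under quantile normalization was written before that value was seen, but for the test of list means, which was itself added after the data were seen. Oestrogen receptor targets had a mean log2 ratio over the 4 days of 0.85 in CAMA1, -0.43 in MCF7 and -0.46 in T47D. The list's mean was higher in 4 of 4 CAMA1 libraries and lower in 8 of 8 of the others. All 4 ratios of a line use its 1 untreated library, so such counts of libraries are not independent observations. By medians T47D day 14 was not lower (0.01, with 18 members higher and 17 lower), and T47D day 10 was at -0.05. Fatty acid synthesis genes had means of 0.22, -0.63 and -0.47, with the same division by means and by medians. The means of both lists kept these directions in every library under quantile normalization and with libraries centred on their medians. Glycolysis genes had -0.0665, 0.26 and -0.38, and the CAMA1 value became 0.05 with centred libraries. The limma test of the difference between lines did not pass for any of these 3 lists (adjusted p = 0.670 for each). CCNE1, the cyclin E1 gene, had 1.75 in MCF7 and -0.32 in T47D, higher in 4 of 4 and lower in 4 of 4 libraries; with quantile normalization 1 T47D library was higher. Its line difference did not pass in limma (adjusted p = 0.831).

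In CAMA1 day 14, 103 genes chosen as high in that library, S100A9, SAA1, CD74 and HLA-DRA among them, had a median log2 ratio of 5.67. Leukocytes in the culture are argued against, since the highest of PTPRC, TYROBP and FCER1G was at 0.34 TPM while CD14 was at 65.9 TPM. MCF7 or T47D cells are argued against too: genes specific to those lines stood at a median of 0.194% (MCF7) and 0.298% (T47D) of their level there. The same genes had a median of 1.24 in MCF7 day 14, which took no part in choosing them, so a rise with time on palbociclib that MCF7 shares may account for part of the pattern. Cells of a line from outside the study were not tested for and stay open.

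In T47D day 7, 99 genes chosen as high in that library, HSPA6 and HMOX1 among them, had a median log2 ratio of 3.11. Cells of CAMA1 or MCF7 are argued against, with genes specific to those lines at a median of at most 0.0328% of their level. At day 7 the medians of these genes were 0.397 in MCF7 and 0.107 in CAMA1, far under the 3.11 of T47D. That value is raised by the choice of genes, so it is no measure for the other lines. Among random lists matched on expression, the MCF7 and CAMA1 medians stood at percentiles 100 and 99.2. A smaller rise at day 7 shared by the lines is therefore not excluded. Stress or handling of that culture cannot be told apart from a passing response of T47D to the drug. Both could give the median of 0.359 found at day 10, and there is 1 library per day. The genes were chosen as higher at day 7 than in the other T47D libraries. A low value at day 10 was thus favoured by the choice and decides nothing.

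Interferon-stimulated and MHC class I lists were called higher at days 7 to 14 than at day 2 by camera, calls lost at adjusted p = 0.145 and adjusted p = 0.212 with an estimated correlation, and 0 members of either passed limma over all genes. Fry called both lists (adjusted p = 0.0137 and 0.0407). By list means, the CAMA1 day 14 library as the whole source is argued against by an adjusted p of 0.00526 for each list without it, although the calls ended without MCF7 (adjusted p = 0.205 and 0.225) and, for MHC class I, without T47D (adjusted p = 0.0712, against 0.0453 for interferon-stimulated genes). By the criterion on the adjusted p, scaling was not excluded (0.0797 for interferon-stimulated genes in the limma test of list means with quantile normalization). The list means went from 1.39 ± 0.31 and 1.18 ± 0.37 to 1.24 ± 0.33 and 1.10 ± 0.39 with quantile normalization. With centred libraries they were 1.30 ± 0.37 and 1.09 ± 0.45. Neither scaling thus removed the differences in size, and the lowest of the 4 lower 95% bounds was 0.099. These bounds are not adjusted over the 30 lists and rest on SEs that may be too small. They do not decide whether scaling gave the whole difference. Whether the lists pass does depend on scaling: the limma p before adjustment over the 30 lists went from 0.00123 and 0.00973 to 0.00419 and 0.0182 with quantile normalization, which took the adjusted p from 0.0243 to 0.0797 for each, and centring took it to 0.0563 and 0.10. Time or density in culture cannot be told apart from the drug, since the interferon score at day 2 was -0.26 relative to untreated and no untreated library kept as long was analysed here.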

How the results depend on the processing

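Leaving out the CAMA1 day 14 library, the T47D day 7 library or both, and the test of list means, were chosen after the data were seen. Counts of called genes are given in the order palbociclib averaged over days, day 2, day 7, day 10, day 14 (each against untreated) and days 7 to 14 against day 2; the reported ones were 872, 19, 263, 387, 568 and 4. With no replicate block for the pairing by cell line they were 5, 0, 0, 0, 2 and 0, and the block changed no list count by over 1.5 times. With no filter on low values they were 570, 10, 112, 194, 261 and 1, and 177 genes differed between lines against 0. Without CAMA1 day 14 they were 1994, 417, 1614, 1583, 308 and 95, and all 872 genes of the averaged comparison were among the 1994. Without T47D day 7 they were 1067, 139, 45, 648, 880 and 1, and without both 2934, 812, 1033, 2758, 950 and 290, with 3 genes differing between lines. Leaving out each line in turn gave ranges of 0 to 616, 0 to 1, 0 to 522, 0 to 80, 0 to 61 and 0 to 0, and 2 to 3 for the difference between lines, with fewer libraries in each fit. Quantile normalization gave 30 at day 2, 611 at day 7 and 614 at day 10. Centring libraries on their medians gave 64, 673, 663 and 893 at days 2, 7, 10 and 14, and 0 for days 7 to 14 against day 2. A pseudocount of 0.1 gave 3 at day 2 and 19 for days 7 to 14 against day 2; a pseudocount of 5 gave 95 and 2, and 23 for the difference between lines, which was 78 with day 2 left out. Apart from the fewer libraries or added genes, the cause was not tested.

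A filter of 5 TPM, limma without trend and robust limma left every count within 1.5 times. Day 14 against day 7 gave 0 genes in limma under every alternative run. Camera called 21 and 20 lists (averaged, and days 7 to 14 against day 2) and, with an estimated correlation, 0 and 0. Fry called 10 and 13. The 10 were mitosis, DNA replication, homologous recombination, lysosome, autophagy, extracellular matrix, immediate-early genes, receptor tyrosine kinase signalling, hypoxia and apoptosis. The limma test of list means called 8 and 14, p53 targets among the 14 without a camera call. For the averaged comparison that test called 7 with quantile normalization and 7 with libraries centred on their medians. Of 134 values of named genes past the threshold, 132 stayed past it with quantile normalization, 79 with no filter, 2 with no replicate block, and 66, 0 and 11 without CAMA1, MCF7 and T47D; 0 of 702 values of named genes reversed while called. Correlations between lines stayed between 0.371 and 0.554. Depth is unknown, so no limit of detection is given for low values.

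For the averaged comparison chance is unlikely but not excluded: 1 of 100 splits of the libraries, the real one, called as many genes (872, the highest other 98). The share cannot be lower than 1 of 100, and the libraries of a line are not independent. For days 7 to 14 against day 2, 2 of 64 splits called as many as 4 genes. The highest other called 133, with CAMA1 day 14, MCF7 day 2 and T47D day 7 as the reference, which points to a structure of the samples. The splits of both comparisons kept 1 library per line in the reference. For each single day 10 splits are too few for a share under 0.05; the real one called 19, 263, 387 and 568 genes and the highest other 0, so that 1 of 10 reached each count. Of these 10, 4 kept 1 library per line in each group, as the real one does (highest other 0), and 6 put a line's pair in the same group and so run across the pairing (highest 0). Day 14 against day 7 has 10 splits too, all 10 reaching its 0, the highest other at 1 among the 4 and at 0 among the 6. For the lists chance was not excluded: 9 of 100 splits reached 21 lists (highest other 24) and 8 of 64 reached 20 (highest other 23).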

Other observations

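The per-line values here were picked after the data were seen, with 1 library per line and day and no test of single libraries. All 4 ratios of a line share its 1 untreated library. Replication-dependent histone genes had medians of -1.16, -1.22, -1.41 and -1.58 (log2 ratio to untreated) at days 2, 7, 10 and 14 in MCF7. Values in CAMA1 and T47D lay between -0.15 and 0.36. Near-identical copies make single histone genes uncertain. How well an mRNA kit captured histone transcripts was not measured, so the list as a whole is uncertain too. Genes of the ATF4 and amino acid response had medians between -1.37 and -1.33 on all 4 days in MCF7, and -0.76, 1.07, -0.01 and -0.89 in T47D. Averaged over the 4 days, the list's mean was 0.04 in CAMA1, -1.30 in MCF7 and -0.0076 in T47D. The limma test of list means for a difference between lines did not pass for histones, the list with the lowest adjusted p (0.392).

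Cholesterol biosynthesis genes had a median of 1.46 in CAMA1 day 14, against 0.41 to 0.47 on the earlier days of that line. In T47D day 7 the unfolded protein response had a median of 1.55. The MTRNR2L genes, near-identical copies of mitochondrial sequence, summed to 8737, 15527, 22043, 32283 and 47311 TPM in CAMA1 (untreated and days 2, 7, 10 and 14), to 7585, 10599, 31879, 17737 and 14847 TPM in T47D, and to between 17738 and 24246 TPM in the 5 MCF7 libraries.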
